A study of Mus musculus with 2 samples.

How the data were processed

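The data are 2 microRNA-seq libraries of total RNA from newborn mouse bladder, 1 per pup, with RNA of a size range under 30 nucleotides per the labels. The authors deposited 1 table per library with whole-number counts per annotated miRNA gene, not normalized and not pooled. Per the labels and the README text deposited with them, reads were aligned to mm10 and genes were those of GENCODE release M4. The aligner, the counting tool and their filters are not given in the sources used here. The tables have no header. For each gene the first count column equalled the sum of the others in both libraries, so the first was read as counts of both strands. The second held nearly all counts and was read as the sense strand, and the third as the opposite strand. This reading comes from the values.

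The first 4 lines of each table are totals of reads not assigned to a gene and stayed out of library sizes and tests. Unmapped reads were 8.19% of reads in pup 1 and 7.32% in pup 2, reads mapped to several places 22.7% and 24.8%, and mapped reads outside the genes on the sense strand 3.22% and 3.07%. Sense-strand counts at genes were 65.9% of reads in pup 1 and 64.8% in pup 2. Reads mapped to several places were listed in a total of their own, apart from the genes, so genes with near-identical copies can be measured too low by an unknown amount.

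Gene symbols, positions and host genes were taken from GENCODE M21 on GRCm38, the assembly that mm10 names, by Ensembl gene number. Of 1973 gene IDs, 1894 matched and 79 did not; the unmatched held 1 sense-strand count in all. Levels are sense-strand counts scaled to 1000000 sense-strand gene counts per library (CPM). The mean and SD over the pups are given. Detection required 1 CPM and 3 counts in both libraries.

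The samples form 1 group of 2 littermates, so no contrast between conditions was possible. The pups were compared with a two-sided exact conditional binomial test per gene, adjusted by Benjamini-Hochberg, over the 362 genes with at least 10 counts summed, with a threshold of 0.05. Library sizes were scaled by TMM in edgeR 4.0.16 (R 4.3.3). Log2 ratios are pup 2 over pup 1 with a prior count of 0.5, and their counting SE covers read counting alone. The biological coefficient of variation is the square root of edgeR's common dispersion in a model with an intercept only. Correlations are across genes on log2(CPM + 1). The 25 lists of cell type markers, families and genomic clusters were fixed before the data were examined, and so were the alternatives except where the text says otherwise. A list's median was set against 10000 random lists of its size, taken from all genes for levels and from genes of like mean expression for ratios. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

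The rule for the named genes, fixed before the data were examined, took the 25 genes with the highest mean CPM and up to 4 members of each list with the highest mean CPM. It also took the 5 highest and 5 lowest log2 ratios among genes with at least 50 counts in each library and an adjusted p of the exact test under 0.05. Lastly it took the 3 genes with the highest opposite-strand share among genes with at least 100 counts in each library, where 7 genes were tied at 100% and their order in the table decided. Genes outside the rule are marked in the text as named after their values were seen, or are members given in list descriptions.

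The binomial test was tested on simulated data before use, with counts drawn from these genes' means and library sizes for the comparison of pup 2 with pup 1 and 200 genes changed, on 363 tested genes. It recovered 34 of 50 genes changed 1.25-fold, 40 of 50 changed 1.5-fold, 46 of 50 changed 2-fold and 49 of 50 changed 4-fold. It called 3 of 163 unchanged genes. The simulated counts for this test held read counting noise alone, with no further spread between libraries. The calls on unchanged genes therefore do not give the rate in the real libraries, whose spread exceeds counting noise. For simulated coefficients of variation of 0.05, 0.1 and 0.2, edgeR gave 0.0508, 0.0972 and 0.191. The alternatives were total count scaling, DESeq2 1.42.0 size factors, other count minimums, unstranded counts, a 2-fold minimum, edgeR's exact test, other pseudocounts, numbered gene copies summed or left out, Mir143 left out of the totals and each pup left out.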

Results

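MicroRNAs, the short RNAs that guide repression of messenger RNAs, were sequenced from whole bladders of newborn mice (postnatal day 0, strain B6NCrl). There were 2 libraries in 1 group, each from 1 bladder of a pup of the same litter, called pup 1 and pup 2 here after their labelled replicate numbers. The sex of the pups was not collected, per the labels. Each library gives counts for 1973 annotated miRNA genes. Pup 1 had 7460621 sense-strand gene counts among 11323636 reads, and pup 2 had 3636650 among 5609988. The sense-strand gene counts of pup 1 were 2.05 times those of pup 2. A count of 0 allows up to 0.402 counts per 1000000 gene counts (CPM) in pup 1 and 0.825 CPM in pup 2. Such limits, and all intervals and counting errors given here, cover counting error only, since the reads carry no molecular identifiers. With 1 group and no treatment, the design allows a description of the tissue's miRNA profile, of its gene lists and of the spread between the littermates. Errors are SDs over the 2 pups (n = 2), and they do not cover differences between litters.

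The first question is which miRNA genes make up the newborn bladder profile. Mir143, a miRNA of smooth muscle, took 52.5% ± 0.23 (SD, n = 2) of all sense-strand gene counts. Mir99a followed at 40708 ± 5119 CPM, 12.9-fold below Mir143. Next came Mir21a at 31210 ± 810.4 CPM, Mirlet7g at 29828 ± 612.2 CPM, Mir322 at 27500.7 ± 59.3 CPM, Mirlet7i at 22500 ± 2206 CPM, Mir26b at 22050.0 ± 1799.6 CPM and Mir126a at 19780.1 ± 190.3 CPM. Mir22, Mir23b, Mir23a, Mir335 and Mir145a had means between 19380.4 and 11981 CPM. Mir130a, Mirlet7d, Mir10b, Mir196b, Mir30e, Mir99b, Mir411, Mir10a, Mir351, Mir429, Mir127 and Mir214 completed the 25 most abundant genes, with means from 8462 to 3954 CPM. This ranking uses sense-strand counts and leaves out loci counted only on the opposite strand. The largest is the one opposite Gm25301, overlapped by Mir378a in GENCODE M21. It had 21363 CPM and as a gene would rank 8. The 10 most abundant genes held 75.6% ± 0.079 of the counts, 32 genes held 90% and 119 genes held 99%. At 1 CPM and 3 counts in both libraries, 335 genes were detected, 240 of them at 10 CPM, 153 at 100 CPM and 66 at 1000 CPM. No count fell on 1305 genes in either library. In counts that include both strands the share of the 10 most abundant genes was 73.5%, and it was 52.6% when Mir143 was left out of the totals.

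**Figure D1:**
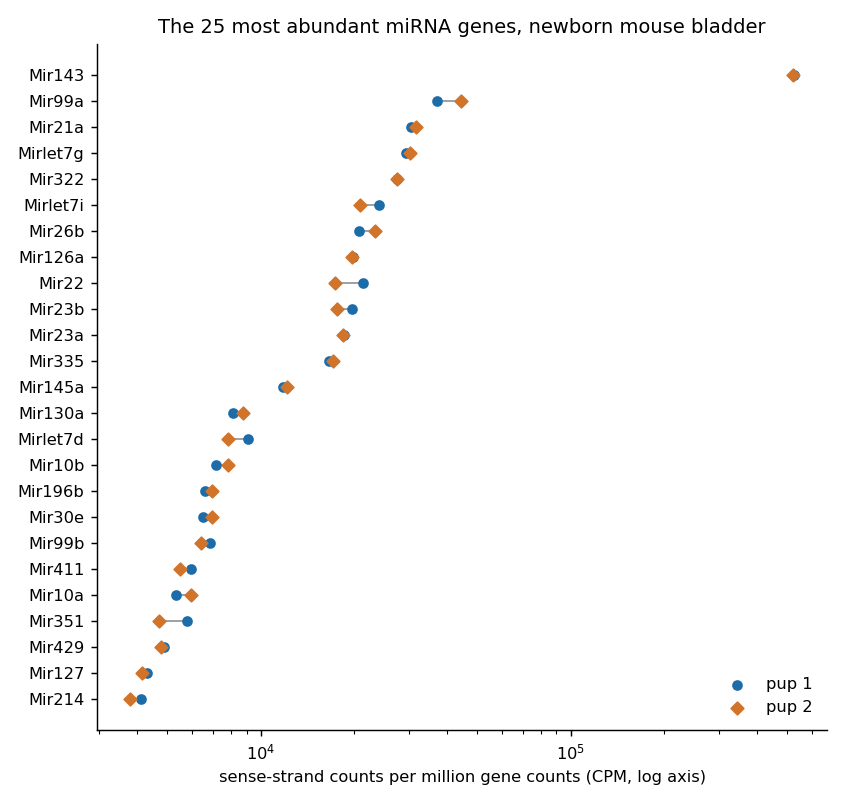
Sense-strand CPM of the 25 miRNA genes most abundant by sense-strand counts, on a log axis, with 1 circle for pup 1 and 1 diamond for pup 2, joined by a line. Mir143 lies 12.9-fold above the second gene, Mir99a, and the points of the pups lie close together for most genes.

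Mir143 (ENSMUSG00000065445.2) lies on chromosome 18 at 61649196 to 61649258 of the GRCm38 assembly, on the minus strand, and Mir145a (ENSMUSG00000065592.1) at 61647825 to 61647894 on the same strand. No protein-coding host gene overlaps either on that strand in the GENCODE M21 annotation. Although these genes are neighbours, Mir143 counts were 43.8 ± 0.92-fold those of Mir145a. Mir99a is on chromosome 16 at 77598936 to 77599000, in an intron of the non-coding gene Mir99ahg. Mir126a is on chromosome 2 at 26591357 to 26591429, overlapping an exon of Egfl7, a gene of endothelial cells. Mir335 is in an intron of the imprinted gene Mest, Mir26b in an intron of Ctdsp1 and Mir10b in introns of Hoxd3 and Hoxd4. Mir196b overlaps an exon of Hoxa9.

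The second question is how the cell types and miRNA families of a bladder are represented, by 25 gene lists fixed before the data were examined. The smooth muscle list, Mir143, Mir145a and Mir145b, summed to 53.7% of all counts. Mir143 alone held 97.8% of that sum, and Mir145b had only 4 and 2 counts. Sums of the lists are shares of miRNA counts and do not measure shares of cells. The epithelium list summed to 2.02%, with 12 of 12 members detected. It was led by Mir429 at 4817 ± 79.9 CPM, Mir205 at 3426 ± 200.7 CPM, Mir203 at 3177 ± 99.9 CPM and Mir200c at 2271 ± 221.3 CPM; Mir429 and Mir200c belong to the miR-200 family of epithelial cells. The fibroblast and mesenchyme list summed to 5.51%, with 7 of 7 members detected, among them Mir21a, Mir22, Mir214 at 3954 ± 222.8 CPM and Mir152 at 255.7 ± 3.93 CPM. Mir21a is also expressed in many other cell types. The endothelium list rests on Mir126a alone, at 1.98% of counts. Blood cell genes summed to 0.178%, at 1201 CPM in pup 1 and 2357 CPM in pup 2. That sum leaves out Mir142, a miRNA of blood cells counted only on the strand opposite Mir142b. With the opposite-strand loci added, an alternative chosen after seeing the data, the list summed to 2000 CPM in pup 1 and 4173 CPM in pup 2, 1.74 times the first sum on average.

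For lists of other tissues the sums were lower, with a limit: Mir124a and Mir9 of neurons and Mir1a and Mir133a of muscle have near-identical copies, whose reads can be missing from the gene counts, so their low counts do not show that they are absent. The multiciliated epithelium list summed to 367.0 ± 2.90 CPM, most of it Mir34c at 254.2 ± 4.09 CPM and Mir449a at 99.9 ± 7.51 CPM. The neuron and glia list summed to 173.3 ± 8.01 CPM, led by Mir338 at 60.8 ± 5.03 CPM and Mir137 at 39.9 ± 3.51 CPM; with numbered copies left out it summed to 104.4 CPM. The intestine and kidney list summed to 125.2 ± 29.0 CPM and the skeletal and cardiac muscle list to 101.8 ± 10.6 CPM, led by Mir208b, which lies in an intron of Myh7. The pancreas and neuroendocrine list summed to 83.6 ± 39.99 CPM, at 55.4 CPM in pup 1 and 111.9 CPM in pup 2, with Mir375 at 48.4 ± 33.9 CPM. Mir122, the main miRNA of hepatocytes and the only member of the liver list, was at 71.7 ± 56.7 CPM, or 111.8 CPM in pup 1 and 31.6 CPM in pup 2. The pluripotent cell list summed to 13.1 ± 0.628 CPM, led by Mir302a at 3.73 ± 0.221 CPM.

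Among miRNA families, let-7 and Mir98 summed to 6.82% of counts, with Mirlet7g, Mirlet7i, Mirlet7d and Mir98 as the most abundant of 10 detected members. Mirlet7a-1, Mirlet7a-2, Mirlet7c-1, Mirlet7c-2 and Mirlet7f-2 share at least 20 bases with another annotated miRNA gene, so their reads can be missing. Mirlet7e has no row of its own here and is not in the sum. The order of the members and the sum are therefore uncertain. The list of Mir99a, Mir99b, Mir100 and the Mir125 genes summed to 5.23%, the list of Mir23a, Mir23b, Mir27a, Mir27b and Mir24-2 to 4.02%, and that of Mir15a, Mir16-1, Mir195a, Mir322 and their relatives to 3.59%. The Mir26 family summed to 2.21%, nearly all of it Mir26b. The Hox-cluster genes Mir10a, Mir10b, Mir196b and others, which lie among the genes that pattern the body axis, summed to 2.02%. The Mir30 family summed to 1.34%, led by Mir30e, Mir30a, Mir30d and Mir30b. The Mir17 cluster and its paralogous clusters summed to 0.923%, led by Mir17 at 3502 ± 388.9 CPM, Mir93, Mir20a and Mir106b. The Mir181 family summed to 0.188%, led by Mir181c and Mir181d, and the Mir29 family to 0.0471%, led by Mir29a at 374.1 ± 47.3 CPM. The limit given for let-7 holds for other families too. The Mir181a and Mir181b genes share at least 20 bases with another annotated miRNA gene, but Mir181c and Mir181d do not. Among others, the Mir30c, Mir29b, Mir125b and Mir16 genes, Mir29c and all measured members of the Mir23a list share them as well. Orders and sums of these lists are uncertain in the same way.

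Imprinted regions were covered by 3 lists. Genes of such regions can be expressed from 1 parental copy, and parental origin was not measured here. The maternally expressed cluster between Dlk1 and Dio3 on chromosome 12 summed to 2.94% of counts, with 43 of 51 measured members detected. It was led by Mir411 at 5731 ± 315.5 CPM, Mir127 at 4226 ± 107.1 CPM, Mir379 at 3122 ± 374.0 CPM and Mir487b at 2538 ± 136.9 CPM. The sum leaves out Mir376a, Mir409, Mir299a and Mir380, which have no row of their own here. Opposite-strand counts at the genes they overlap came to 1716, 1511, 1232 and 551 CPM. Other imprinted loci, with Mir335 at 16873 ± 407.3 CPM, Mir296, Mir298 and Mir483, summed to 1.96%. The cluster in an intron of Sfmbt2 summed to 0.380%, with 9 of 33 measured members detected, led by Mir467d, Mir467e, Mir467c and Mir669o. Nearly all of its measured members share at least 20 bases with another annotated miRNA gene, so their reads can be missing. Its sum and the number detected are therefore uncertain and do not show low expression.

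The median member of 23 of the 25 lists lay above the 95th percentile of 10000 random lists of the same size; the exceptions were the liver and Sfmbt2 intron lists. This is a weak comparison, because most annotated genes were at 0 in both libraries. Members with near-identical copies, such as Mir26a-1 at 8.15 ± 0.914 CPM and Mir26a-2 at 28.9 ± 1.19 CPM beside Mir26b, are uncertain, since 22.7% of reads in pup 1 and 24.8% in pup 2 mapped to several places and were listed apart from the genes.

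**Figure D2:**
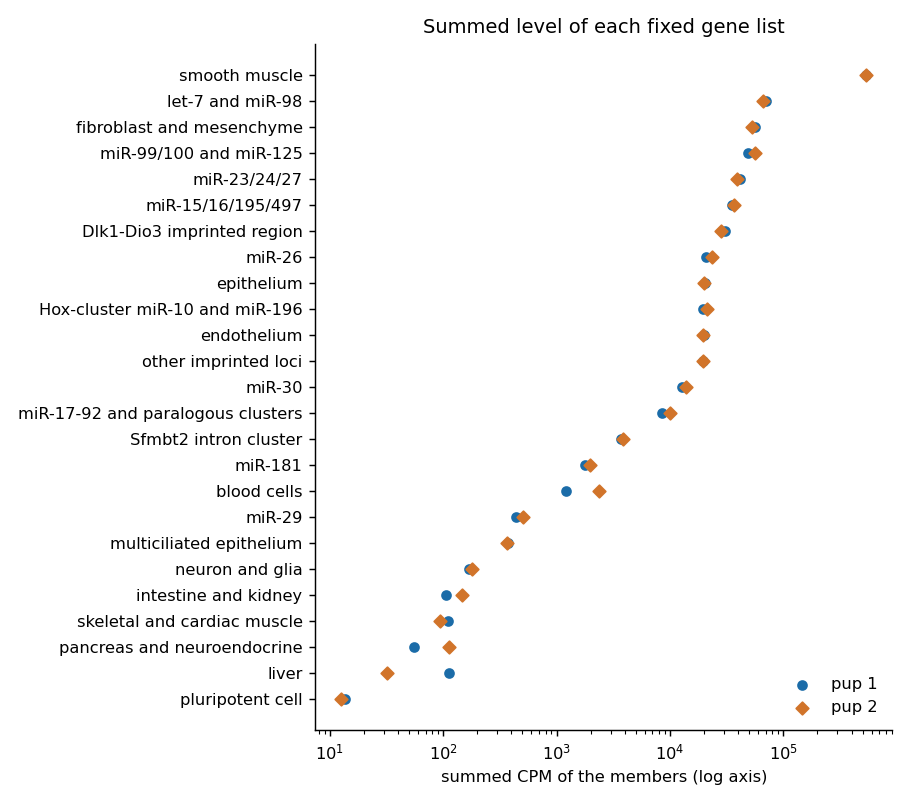
Summed CPM of the members of each of the 25 gene lists on a log axis, with 1 circle for pup 1 and 1 diamond for pup 2. The smooth muscle list stands at 53.7% of counts, and the lists of blood cells, liver, pancreas, and intestine and kidney show the widest gaps between the pups.

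The third question is how far the littermates resembled each other. Across the 362 genes with at least 10 counts summed over both libraries, log2(CPM + 1) of the pups had a Pearson r of 0.995 and a Spearman rho of 0.9899; genes are not independent replicates, so no p is given. The median absolute log2 ratio between the pups was 0.163, or 1.12-fold. The spread between the pups beyond read counting corresponded to a biological coefficient of variation of 13.2% by edgeR. With 1 library per pup, this spread cannot be split into differences between animals and differences in sample handling or library preparation. The chi-square of the counts was 48.3 times its 361 degrees of freedom, so the tables are not 1 library deposited in duplicate. This shows no more than that, and the pups were kept as 2 samples because the labels name them as 2 animals.

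The fourth question is which genes differed between the libraries of the littermates. Mir223, a miRNA of neutrophils and other myeloid cells, was higher in pup 2, at 1274 CPM against 396.2 CPM in pup 1 (log2 ratio 1.71, counting SE 0.034). It lies on chromosome X at 96242817 to 96242926. Mir122 was higher in pup 1, at 111.8 CPM against 31.6 CPM (log2 ratio -1.79, counting SE 0.143). Mir375, a miRNA of endocrine cells, was higher in pup 2, at 72.3 CPM against 24.4 CPM (log2 ratio 1.59, counting SE 0.139), and so was Mir215 at 28.0 CPM against 13.8 CPM (log2 ratio 1.05). Mir20b and Gm23935 were higher in pup 2 with log2 ratios of 0.83 and 0.80. Mir770 in the non-coding gene Meg3, Mir7j, Mir208b and Mir187 were higher in pup 1, with log2 ratios of -0.61, -0.57, -0.45 and -0.435.

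By a two-sided exact binomial test per gene with Benjamini-Hochberg adjustment, 117 of the 362 genes differed between the libraries, 69 higher in pup 2 and 48 higher in pup 1. With DESeq2 size factors the split was 56 and 69, and with total count scaling 59 and 64, so the direction of small ratios depends on the scaling; Mir143, at a log2 ratio of 0.01, is such a gene. Of the 117 genes, 10 differed at least 2-fold, 7 of them higher in pup 2. This test compares these libraries with read counting noise alone and not a condition. With the common dispersion of these same libraries in edgeR's exact test, 5 genes stayed under the threshold, and 3 to 6 under other scalings, count minimums and unstranded counts. With 1 library on each side no residual degree of freedom is left, so this count describes these libraries and tests no difference between animals. The genes were Mir223, Mir122, Mir375 and, named after their values were seen, Mir147 and Mir1264, which had 20 and 40 counts and 2 and 12 counts in pups 1 and 2. Mir1264 was not among them with total count scaling, DESeq2 size factors or no filter, and neither Mir147 nor Mir1264 reached the minimum of 100 counts. Comparing 2 values with 2 others by exact permutation could not go below p = 0.33, and here there is 1 library on each side.

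**Figure D3:**
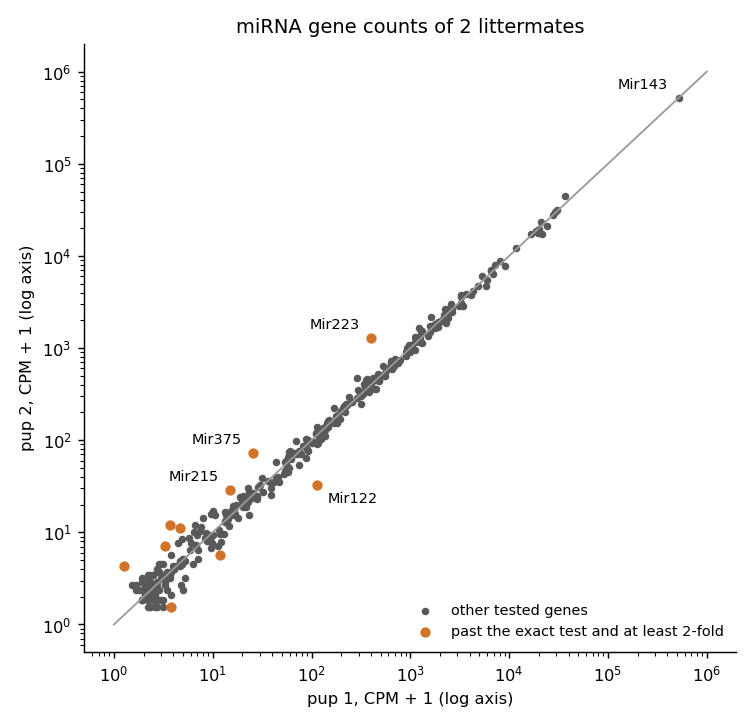
CPM plus 1 in pup 2 against pup 1, on log axes, for the 362 tested genes, with the line of equal values. The 10 genes past the exact binomial test and at least 2-fold apart are orange, and Mir223 and Mir122 lie far from the line on opposite sides.

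The share of genes past the exact binomial test depends on depth, with 117 of all 362 tested genes but 121 of 248 at a minimum of 100 counts, so the counts per list do not show that a list stands apart from other genes of like depth. In the blood cell list, 3 of 6 tested members passed the test, all higher in pup 2. They were Mir223, Mir144 (471.0 against 288.3 CPM) and Mir451a (452.3 against 357.1 CPM). Mir144 and Mir451a are miRNAs of red cells and are neighbours on chromosome 11, so they are not separate evidence. Mir155, Mir486 and Mir150 did not pass, with log2 ratios of -0.10, 0.13 and 0.16. The intestine and kidney list had 3 of 4 members that passed as higher in pup 2, Mir215, Mir192 and Mir194-1. In the pancreas and neuroendocrine list, Mir375 and Mir7b passed as higher in pup 2. In the Mir17 list, 8 of 14 members passed as higher in pup 2 and none as lower. The log2 ratios were 0.25 for Mir17 and 0.45 for Mir93. By the sign of the ratio alone, 11 members of that list were higher in pup 2 and 3 in pup 1. In the region between Dlk1 and Dio3, 16 of 44 members passed as higher in pup 1 and none as higher in pup 2. The 16 include Mir379 (log2 ratio -0.22) and Mir411 (-0.09). By sign alone, 36 of the 44 members were higher in pup 1 and 8 in pup 2. Adjusted over the list alone, the counts of differing members were 3 for blood cells, 3 for intestine and kidney, 2 for pancreas, 8 for the Mir17 list and 17 for the region between Dlk1 and Dio3. In the skeletal and cardiac muscle list, Mir208b passed as higher in pup 1 and Mir499 as higher in pup 2. With the common dispersion, the list members left were Mir223, Mir375 and Mir122, and none of the Mir17, intestine and kidney, or Dlk1 to Dio3 lists.

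Against 10000 random lists matched on mean expression, the median log2 ratio of 8 of the 25 lists lay outside the central 95%. The random lists are drawn gene by gene, while log2 ratios of genomic neighbours lay closer together (mean absolute difference 0.25) than those of permuted clusters (0.32), so for lists made of neighbours, such as the Mir17 clusters and the region between Dlk1 and Dio3, the random range can be too narrow. One of these, the liver list, is Mir122 alone (-1.79), set against draws that include Mir122 and equal to their lower bound, so it is no comparison. The others were the lists of blood cells (median 0.26), intestine and kidney (0.72), pancreas and neuroendocrine (0.62), the Mir17 clusters (0.20), skeletal and cardiac muscle (-0.45, but 0.33 in counts of both strands and -0.18, inside, with no count filter), the region between Dlk1 and Dio3 (-0.11, 36 of 44 members higher in pup 1) and other imprinted loci (-0.19). For other imprinted loci the log2 ratio of the summed counts was 0.04, of the opposite sign, because Mir335 holds most of them. Without the member with the most extreme ratio, an alternative chosen after seeing the data, 4 lists lay outside: the Mir17 clusters, skeletal and cardiac muscle, the region between Dlk1 and Dio3, and liver, which has no member to spare. The lists of blood cells (0.16), pancreas and neuroendocrine (0.25), intestine and kidney (0.38) and other imprinted loci (-0.17) then lay inside.

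The fifth question is how the counts fall on the strands. The columns carry no header, and the strand of each was read from the values. Counts on the strand opposite to the annotated gene made up 3.17% of gene counts in pup 1 (exact 95% interval 3.16% to 3.19%) and 3.18% in pup 2 (3.17% to 3.20%). Among genes with at least 100 counts in each library, Gm24083, Mir142b and Gm25750 had 100% of their counts on the opposite strand in both; Gm25301, Gm25927, Gm25252 and Gm24321, tied with them and named after their values were seen, did too. The opposite-strand counts at Gm25301 came to 21363 ± 252.4 CPM of the sense total, which as a gene would rank 8. Those at Mir142b, on chromosome 11 at 87756841 to 87756955, came to 799.1 CPM in pup 1 and 1816 CPM in pup 2.

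**Figure D4:**
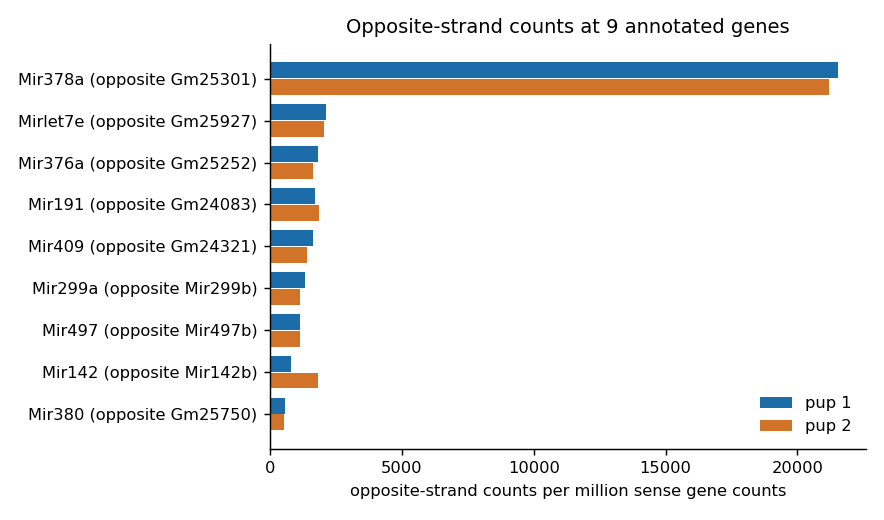
Counts on the strand opposite to 9 annotated genes, as CPM of the sense-strand total, with 1 bar for pup 1 and 1 bar for pup 2; labels give the overlapping M21 gene first. The bar opposite Gm25301 stands at 21363 ± 252.4 CPM on average, and the one opposite Mir142b is higher in pup 2.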

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

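Each test reported here was chosen after its result was seen, except that of other myeloid genes, which was written before.

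Counts on the opposite strand, which the comparisons of the profile do not use, lay far above the limit that a count of 0 allows at 9 annotated genes with next to no sense-strand counts. At Gm25301 there were 160715 counts in pup 1 and 77042 in pup 2. Gm25927 had 15848 and 7470, Gm25252 had 13510 and 5896, and Gm24083 had 12831 and 6820. Gm24321 had 12156 and 5061, Mir299b had 9916 and 4127, and Mir497b had 8412 and 4128. Mir142b had 5962 and 6605, and Gm25750 had 4248 and 1939. These 9 genes held 99.6% of opposite-strand counts in each library, with 7 sense-strand counts in all.

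The tables argue against loss of strand in library preparation, which would put opposite-strand reads at all abundant genes: the 100 most abundant sense-strand genes had at most 0.00099% of their counts on the opposite strand. A candidate explanation is that these reads come from miRNA genes which the older annotation lacks. In GENCODE M21, 32 of the genes are overlapped on the other strand by a miRNA gene with no row of its own here, and at least 99.97% of opposite-strand counts fell at those 1.62% of genes. The overlapping genes are Mir378a, Mirlet7e, Mir376a, Mir191, Mir409, Mir299a, Mir497, Mir142 and Mir380, in the order of the genes above. No biological explanation was tested, since the design has 1 group.

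Mir223 and the Mir142 locus, both of blood cells, were higher in pup 2, by log2 ratios of 1.71 and 1.21. A difference in depth or scaling does not account for it, since scaling moves all genes alike. The 97 genes within 4-fold of Mir223 had a central 95% of log2 ratios up to 0.41. Their median of 0.027 lies near 0 through the TMM scaling itself. Mir223 was picked for its high ratio, so its place outside that range is no test. With total counts and with DESeq2 size factors, edgeR gave Mir223 a log2 ratio of 1.68. More whole blood in pup 2 as the whole cause would raise the red cell genes about as much. Mir451a and Mir144 were both higher in pup 2, by 0.37 and 0.73, less than Mir223 and the Mir142 locus. The other blood cell genes Mir486, Mir150 and Mir155 had 0.13, 0.16 and -0.10. The bound set for Mir451a was 1.35, the log2 ratio of Mir223 less 2 SDs of the genes of like level. It rests on a gene picked for its high ratio, and the Mir142 locus, at 1.21, lies below it too. The bound therefore cannot exclude whole blood, which stays open as the cause or a part of it. More myeloid cells in pup 2 may still be the reason: Mir511 and Mir146 (also called Mir146a) had a median log2 ratio of 0.47, between the values named in advance for and against it, and with few counts; Mir146b, also named in advance, had 3 and 0 counts, and with it the median is 0.32. No other biological explanation was tested.

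Genes with near-identical copies had lower counts on average than other list members. Some that share at least 20 bases were abundant, such as Mir23b at 18650 CPM, Mir23a at 18514 CPM and Mir411 at 5731 CPM. Within the fixed lists, the 96 genes sharing at least 20 bases with another annotated miRNA gene differed in log2(CPM + 1) from the 127 others by -2.88 on average (permutation p = 0.0001, the smallest the permutations can give). The permutations moved the sharing label gene by gene, while copies of 1 miRNA share bases with each other and are not independent. This p can therefore be too small. Among members at 1 CPM or more the difference was -3.10, so unexpressed annotation entries do not account for it. Reads shared between copies and left out of the counts are a candidate explanation, in line with the 22.7% and 24.8% of reads mapped to several places. Lower expression of such genes was not tested and stays open.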

How the results depend on the processing

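The alternatives were set before the data were examined, except those that leave out the most extreme list member or count opposite-strand loci. The 117 genes differing fell to 10 at a 2-fold minimum and to 5 by edgeR's exact test, by construction of stricter tests; that test gave 4 with total counts, DESeq2 size factors or no filter, 3 at a minimum of 100 counts and 6 in unstranded counts, where Mir142b is added; other scalings and count minimums gave 118 to 125. Chi-square over its degrees of freedom was 26.6 with no filter, since low genes add degrees of freedom. The share of the 10 most abundant genes was 73.5% in unstranded counts, 52.6% without Mir143 in the totals, and 73.5% with opposite-strand loci as genes. Lists with a median ratio outside the central 95% numbered 4 without the most extreme member, as the lists of blood cells, pancreas, intestine and kidney, and other imprinted loci came inside. The median log2 ratio of the skeletal and cardiac muscle list, -0.45, became 0.33 in unstranded counts, of the opposite sign, by construction: Mir1b, with 10 and 2 sense-strand counts, gains 24 and 19 opposite-strand counts and goes from -1.01 to 0.37, which moves the median of 5 members from Mir208b to Mir208a. Leaving out 1 pup gave 351 to 355 genes detected, a top 10 share of 75.7% in each, and an opposite-strand share of 3.17% to 3.18%. Leaving out 1 of 2 pups moves a mean over the pups by less than 1 SD whatever the values, so for the opposite-strand share, CPM and list sums it is no check of stability. Without pup 2 the pancreas and neuroendocrine list summed to 55.4 CPM, 0.66 times its mean; the liver list summed to 111.8 CPM without pup 2 and 31.6 CPM without pup 1. No paired analysis was possible because there is 1 group. Of 102 named genes' CPM, 25 moved by more than 1 SD in unstranded counts and 1 under TMM. All 25 list sums moved without Mir143 in the totals, 6 in unstranded counts, 4 with copies left out (neuron and glia to 104.4 CPM) and 3 with opposite-strand loci added (blood cells to 3087 CPM). The 10 named log2 ratios kept their direction and call in 5 alternatives of scaling, filter and strand; by edgeR's exact test Mir223, Mir122 and Mir375 kept the call and the other 7 lost it, with the same direction. Genes under about 0.825 CPM are not measurable in pup 2 at this depth.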

Other observations

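The tests in this part were chosen after the list members' values were seen.

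In the list of the Mir15 and Mir16 family, 5 of 7 members were higher in pup 2 and 1 in pup 1 by the exact binomial test, which compares these libraries with counting noise alone. With total counts the split was 4 and 1, and with DESeq2 size factors 4 and 2. The list's median log2 ratio, 0.13, was inside the central 95% of random lists, and no member stayed under the threshold with the common dispersion. Mir16-1 was at 2180 CPM in pup 2 against 1604 CPM in pup 1 (log2 ratio 0.47), Mir15a had a log2 ratio of 0.28, Mir16-2 of 0.36, Mir322 of 0.02, a sign that depends on the scaling, and Mir503 of -0.14, and Mir195a, at 0.05, did not pass. In the region between Dlk1 and Dio3, the opposite-strand loci Mir376a, Mir409, Mir299a and Mir380 had 0.895, 0.854, 0.854 and 0.936 times the CPM in pup 2 that they had in pup 1.

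One hypothesis is that genes of 1 genomic cluster share a ratio between the pups, as genes of 1 primary transcript could. Among 44 clusters of 153 tested genes on the same strand within 10000 bases of the next, the mean absolute difference of log2 ratios within a cluster was 0.25, against 0.32 for permuted clusters (one-sided permutation p = 0.0082). The same comparison for levels gave a mean absolute difference of 3.18 in log2(CPM + 1), against 3.98 for permuted clusters (one-sided permutation p = 0.0068). So neighbours were closer than chance pairs but still far apart in level. The median cluster spanned a 10.9-fold range of levels, and Mir143 and Mir145a spanned 43.8-fold. The permutations did not match genes on level, and ratios of genes with few counts vary more. Like levels within clusters could therefore bring ratios closer without a shared ratio, so the comparison cannot decide the hypothesis.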
